A study of Mus musculus with 8 samples.

How the data were processed

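RNA of macrophages sorted from lung was analysed in 8 libraries, 4 from recipients of Tgfbr2-floxed marrow (WT) and 4 from recipients of Tgfbr2-floxed marrow with Cre in Lyz2 (Tgfbr2_KO), 10 days after 50 ng of diphtheria toxin and 1 month after transplantation. Per the labels, RNA was extracted with TRIzol and libraries were made with a stranded mRNA kit and read on a NovaSeq. The deposited values are estimated counts per gene, which the authors made with salmon and merged into 1 table, with no scaling for library size as far as the values show. Between 81.8% and 84.8% of the values of a library were whole numbers. The labels name GRCm38 and DESeq2 1.40.1. The salmon version, strand setting, transcript annotation and filters are not given in the sources used here.

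The table held 22597 genes, of which 22580 had an identifier in GENCODE M21 and 21871 were protein-coding there, so totals are sums over these genes and not sequencing depth. Totals were between 15597300 and 37654100 counts, and 3 counts, used as the floor, were 0.0797 to 0.192 CPM. 5312 genes had 0 counts in every library and 32 symbols named more than 1 gene.

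Counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 12750, and scaled by TMM. Genotypes were compared with the robust edgeR quasi-likelihood F-test with group only, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM are TMM-scaled, errors of fold changes are standard errors (SE), errors of means are standard deviations (SD) and intervals are at 95%. Principal components used log2 CPM with a prior count of 2, and exact permutation tests compared their scores.

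Gene lists were tested with limma camera at a preset correlation of 0.01, adjusted over 38 lists. They were TGF-β receptors and Smads, ligands and activation, induced genes and microglial dependent genes, shared, CD206-positive and CD206-negative interstitial macrophage genes, classical and non-classical monocytes, MHC class II, transcription factors, inflammatory, M2-associated, type I interferon, interferon-γ, chemokine, trafficking receptor, lipid-associated, matrix, efferocytosis, complement, LXR, cholesterol, glycolysis, oxidative phosphorylation, lysosome, cell cycle, ribosomal and immediate-early genes, and markers of alveolar macrophages, dendritic cells, neutrophils, lymphocytes, eosinophils with basophils and mast cells, endothelium, epithelium, fibroblasts and platelets with erythroid cells. They held 936 genes, 923 in the table and 858 tested, with 161 in 2 or more lists.

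The samples, groups, tests, lists, the rule for named genes and the alternatives in scaling, filter, tool, fold, block, set test and left-out library were chosen before the data were examined. The rule named Tgfbr2 and Lyz2, up to 12 genes per direction with the largest change among those past the threshold with at least 10 CPM in a group and no overlap, up to 4 genes of each list with the smallest adjusted p, and 18 markers. Predicted genes were passed over, and some genes that the rule names are not reported here. Sftpc, Pecam1, Col1a1, Ddx3y, Gpnmb and Ccl2 were named after their values were seen. The library sets and the alternatives that use them were chosen after seeing the data. Recovery of known changes was tested on simulated data.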

Results

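The libraries hold the polyadenylated RNA of macrophages sorted from mouse lung as interstitial macrophages, the macrophages that lie in the lung tissue outside the air spaces. The recipients were irradiated mice whose own interstitial macrophages could be deleted with diphtheria toxin. They received bone marrow either from Tgfbr2-floxed donors (WT) or from Tgfbr2-floxed donors that also carried Cre in the Lyz2 gene (Tgfbr2_KO), which deletes the floxed part of Tgfbr2, the type II receptor of TGF-β, in myeloid cells. After 1 month a dose of 50 ng diphtheria toxin was given to empty the niche, and the macrophages were taken 10 days later. How far the niche was emptied was not measured here. There were 4 libraries per genotype, named WT 1 to 4 and KO 1 to 4, and the comparison asks what macrophages that refill the niche express when this receptor is deleted. Only the KO donors carried Cre, so effects of Cre cannot be told apart from loss of the receptor for any gene. The gene counts summed to between 15597300 (WT 1) and 37654100 (WT 4) per library. Nothing in the labels says whether each library came from its own mouse, so p-values measure only the spread between these libraries, which may be technical.

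Lung epithelial, endothelial and fibroblast transcripts separated 3 libraries, WT 1, WT 2 and KO 1, from the other 5. Sftpc, which encodes surfactant protein C of alveolar type 2 cells, was at 1780, 1593 and 2815 CPM in WT 1, WT 2 and KO 1, against 67.9 to 103 CPM in the others. Pecam1, an endothelial adhesion molecule, was at 467, 395 and 726 CPM in these 3 and at 25.1 to 35.1 CPM in the others. Of the 80 tested genes of the epithelial, endothelial and fibroblast lists, 71 were higher in each of the 3 libraries than in each of the other 5. These libraries are called lung-rich below, and both genotypes occur in both sets: 1 KO and 2 WT libraries were lung-rich, 3 KO and 2 WT were not. Within the lung-rich set, epithelial genes held 0.84% of the counts in KO 1 against 0.53% in WT 1 and 0.46% in WT 2. Endothelial genes held 1.13% against 0.75% and 0.55%. Fold changes within this set thus compare libraries with unequal shares of lung transcripts. The sets were defined after the data were seen and are not groups of the study. Values within each set, and from a fit with the set as a term, therefore stand beside the pooled ones. Within the other 5 libraries, replicates lay very close together. WT 3 and WT 4 had a median chi-square of their counts 1.75 times that of counting noise, against 3.99 for WT 1 and WT 2, and 2.01 to 2.69 between KO 2, KO 3 and KO 4. They differed by more than counting noise and were kept as separate libraries. If they are not independent, errors in fits of the 5 libraries and in fits with the set term are too small.

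**Figure D1:**
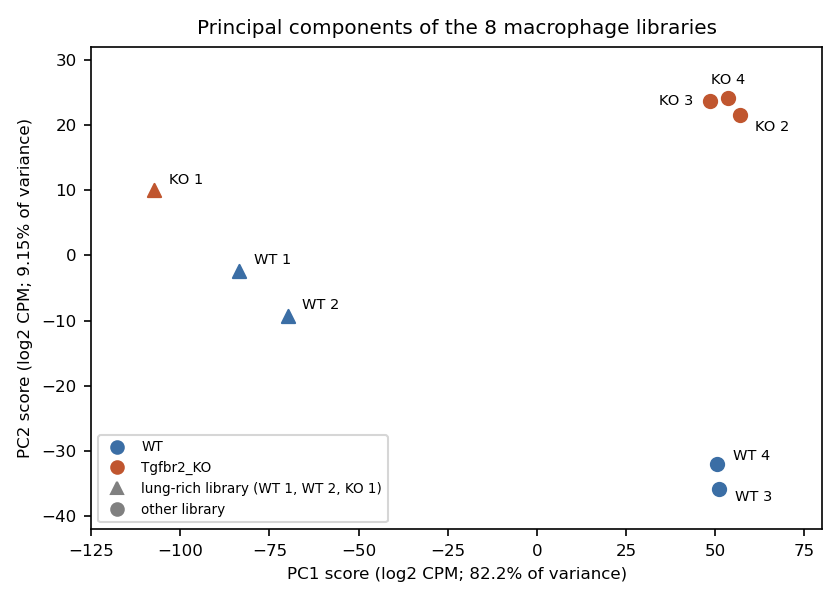
Scores of the 8 libraries on the first and the second principal component of log2 CPM, with WT in blue, Tgfbr2_KO in red, the lung-rich libraries as triangles and the others as circles. The lung-rich libraries lie between -107 and -69.9 on the first component and the others between 48.5 and 57.0, while on the second component all Tgfbr2_KO libraries lie above all WT libraries.

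Tgfbr2 (ENSMUSG00000032440, GRCm38 chromosome 9, 116084293 to 116175360, minus strand) was not lower in the libraries labelled knockout at the level of the whole gene. It was at 548, 474, 546 and 542 CPM in WT 1 to 4 and at 424, 576, 529 and 539 CPM in KO 1 to 4. The log2 fold change was -0.03 (SE 0.12, 95% interval -0.30 to 0.24, edgeR adjusted p = 1.00), with 0.01 in the 5 other libraries and -0.33 in the lung-rich ones. Which exons Cre removes is not given in the sources used here. The longest internal exon makes up 800 of 3476 bp of one annotated transcript and 800 of 8092 bp of the other, so a gene total can keep most of its reads after an exon is lost, and it checks the genotype labels only weakly. Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321, minus strand), which encodes lysozyme and carries Cre in the KO donors, was lower in each library labelled knockout than in every WT library. It was at 7285, 8262, 12935 and 13193 CPM in WT 1 to 4 and at 3440, 5611, 5448 and 5538 CPM in KO 1 to 4. Each KO library held between 41.7% and 44.3% of the mean of the WT libraries of its own set. The pooled log2 fold change of -1.06 (SE 0.27) did not pass (edgeR adjusted p = 0.191), and with the library set as a term it was -1.22 (SE 0.07, edgeR adjusted p = 1.47e-04).

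**Figure D2:**
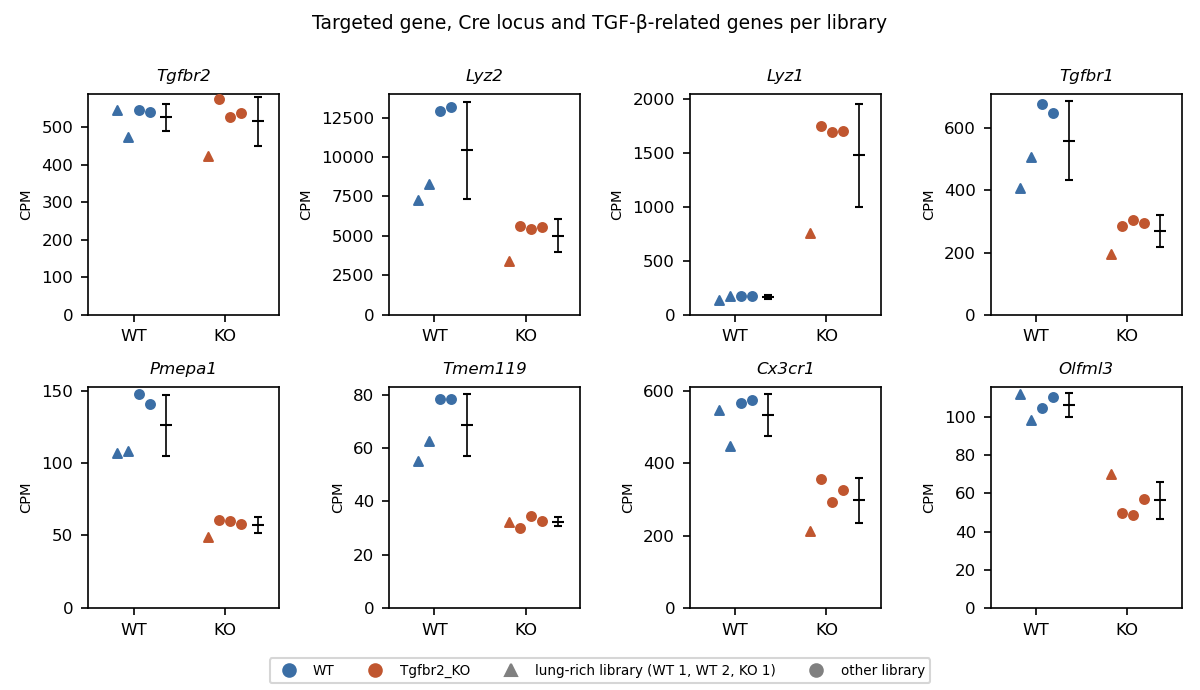
CPM of Tgfbr2, Lyz2, Lyz1 and 5 genes related to TGF-β or to microglia in each library, with the mean and SD of each genotype as bars (n = 4) and lung-rich libraries as triangles. Tgfbr2 overlaps between the genotypes, while Pmepa1 lies between 49.0 and 61.0 CPM in the KO libraries and between 107 and 148 CPM in the WT libraries.

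Over all 8 libraries, Cd209f, Cd209g, F13a1, Folr2 and Ccl24 of the CD206-positive macrophage genes rose in Tgfbr2_KO, and the TGF-β target Pmepa1 and the microglial genes Tmem119 and Olfml3 fell. The C-type lectins Cd209f and Cd209g rose most. Cd209f was at 112 ± 32.8 CPM in Tgfbr2_KO against 5.50 ± 2.58 in WT (SD, n = 4 each), a log2 fold change of 4.35 (SE 0.44, edgeR adjusted p = 0.0273). Mmp9, a gelatinase that cleaves matrix, was at 1044 ± 302 CPM against 90.5 ± 18.4 (log2 fold change 3.53, SE 0.29, edgeR adjusted p = 0.0197). Coagulation factor XIII subunit F13a1 was at 1145 ± 440.5 against 209.6 ± 32.4 CPM (2.45, SE 0.35), the folate receptor Folr2 at 265.5 ± 96.6 against 56.4 ± 5.12 CPM (2.23, SE 0.31), and the eosinophil chemokine Ccl24 at 41.4 ± 17.6 against 4.90 ± 0.95 CPM (3.08, SE 0.39). The other risers of the 12 largest were Cd209g, Lyz1, Mucl1, Slc12a5, Trim30c, Gprc5c and C1qtnf1, with log2 fold changes from 2.09 (C1qtnf1) to 4.42 (Cd209g).

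Among the genes that fell, Pmepa1, a TGF-β target that restrains Smad signalling, was at 57.1 ± 5.48 CPM in Tgfbr2_KO against 126 ± 21.3 in WT (SD, n = 4 each; log2 fold change -1.14, SE 0.14, edgeR adjusted p = 0.0314). Tmem119, a microglial surface protein that interstitial macrophages also express, was at 32.4 ± 1.76 against 68.8 ± 11.7 CPM (-1.09, SE 0.13, edgeR adjusted p = 0.0289). Olfml3, another gene high in microglia, changed by -0.91 (SE 0.12). Itgav, the αV integrin chain that takes part in releasing active TGF-β, changed by -0.72 (SE 0.09). Zfp691 fell most (-1.41, SE 0.19), and Ggta1, Spata13, Mvb12b, Extl3, Fam110a, Synj2 and Nbeal2 fell by 0.42 (Nbeal2) to 0.92 (Ggta1) on the log2 scale.

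In all, 25 genes were higher and 13 lower in Tgfbr2_KO among 12750 tested (edgeR quasi-likelihood test, adjusted p under 0.05), and all 38 had non-overlapping genotypes. The log2 fold changes in the 5 other libraries and in the lung-rich ones, where only KO 1 carries the KO label, were 2.71 and 1.15 for F13a1, 2.60 and 0.92 for Folr2, and 5.30 and 2.96 for Cd209f. With the library set as a term, 1095 genes were higher and 1006 lower, and in the 5 other libraries alone 2493 and 2363, with all 38 among them in both. Across genes, which are not independent replicates, the log2 fold changes of the 2 sets correlated at 0.22 over 12566 genes. Of the genes called higher in the 5 libraries, 51.8% were also higher in KO 1 than in WT 1 and WT 2, and of those called lower 72.2% were also lower. Over all genes tested in the lung-rich libraries the median log2 fold change was -2.05e-04, so about as many genes lay above 0 as below. The share of risers that agreed was thus close to that of genes at large. A fit with the set as a term assumes the same genotype effect in both sets. The pooled calls ended, with 0 genes either way, when any single library other than KO 1 was left out, while 807 to 1451 genes had an unadjusted p under 0.05. Without KO 1 there were 619 and 241 calls. With WT 3 and WT 4 summed into 1 library and KO 4 left out, the set-adjusted counts were 70 and 115. In that fit F13a1 and Folr2 did not pass (edgeR adjusted p = 0.078 and 0.0887). Cd209f, Cd209g and Ccl24 passed (edgeR adjusted p = 0.0346, 0.0346 and 0.033). Trim30c, Ggta1 and Nbeal2 did not pass either (edgeR adjusted p = 0.0586, 0.0557 and 0.054).

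**Figure D3:**
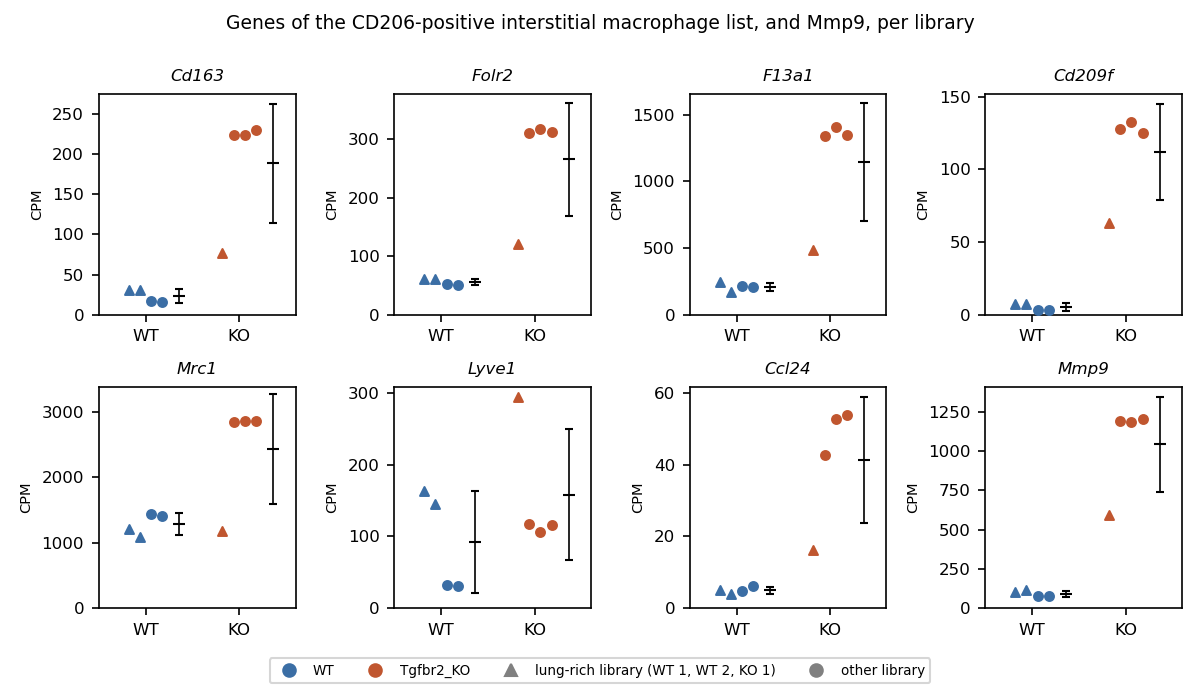
CPM of 7 genes of the CD206-positive interstitial macrophage list and of Mmp9 in each library, with the mean and SD of each genotype as bars (n = 4) and lung-rich libraries as triangles. F13a1 was at 485 CPM in KO 1 and at 1343 to 1404 CPM in KO 2 to 4, against 170.3 to 249 CPM in WT, while Mrc1 in KO 1 (1174 CPM) lay within the WT range.

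The list of CD206-positive interstitial macrophage genes, the perivascular kind marked by the mannose receptor, had camera adjusted p = 1.38e-34 (higher) with the preset correlation, and adjusted p = 0.12 with an estimated correlation. Of its 28 tested genes 5 rose (Cd209f, Cd209g, Ccl24, F13a1 and Folr2), 0 fell and 23 did not pass, 22 rose when adjusted over the list alone, and the mean log2 fold change was 1.74. With the library set as a term 24 of the 28 rose and 0 fell (median 1.57; adjusted p = 0.145 with an estimated correlation), and in the 5 other libraries 27 rose (median 1.94; adjusted p = 0.0187 with an estimated correlation). The haemoglobin scavenger receptor Cd163 was at 188 ± 74.0 against 23.6 ± 8.52 CPM (SD, n = 4 each; log2 fold change 2.999, edgeR adjusted p = 0.0514), and its log2 fold change was 2.97 with the set term (edgeR adjusted p = 0.00712), 3.81 in the 5 other libraries and 1.26 in the lung-rich ones. Cd163 did not pass with the set term when WT 3 and WT 4 were summed and KO 4 was left out (2.53, edgeR adjusted p = 0.109). Mrc1, which encodes CD206 itself, had a log2 fold change of 0.92 (edgeR adjusted p = 0.291). It was 0.67 with the set term (edgeR adjusted p = 0.0432), 1.01 in the 5 other libraries and -0.03 in the lung-rich ones. With WT 3 and WT 4 summed and KO 4 left out, Mrc1 did not pass with the set term (0.49, edgeR adjusted p = 0.351). KO 1 is the only lung-rich KO library and had the largest share of lung transcripts. The difference in Mrc1 was thus not seen in both sets, and the lung-rich value rests on that library. Lyve1, a hyaluronan receptor of these macrophages and of lymphatic endothelium, had 0.77 (edgeR adjusted p = 0.905) and 1.52 with the set term (edgeR adjusted p = 0.00184), and it was highest in the lung-rich libraries of each genotype.

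The list of CD206-negative interstitial macrophage genes, the antigen-presenting kind, had camera adjusted p = 2.25e-04 (lower) with the preset correlation, and adjusted p = 0.674 with an estimated correlation. Without KO 1 the list did not pass (camera adjusted p = 0.641). Of its 22 tested genes 0 rose, 1 fell (Tmem119) and 21 did not pass, 2 fell when adjusted over the list alone, and the median log2 fold change was -0.15. With the set term 13 of the 22 fell and 0 rose. Cx3cr1, the fractalkine receptor, was at 298 ± 62.0 CPM in Tgfbr2_KO against 535 ± 58.5 in WT (log2 fold change -0.84, edgeR adjusted p = 0.128, and 0.00145 with the set term). The integrin Itgax, which encodes CD11c, had -0.93 (edgeR adjusted p = 0.522, and 0.00194 with the set term). The MHC class II chain H2-Ab1 had -0.05 and the cytokine gene Il1b -0.16 (edgeR adjusted p = 1.00 for both). Genes shared by interstitial macrophages did not pass as a list (camera adjusted p = 0.816, median log2 fold change -0.02, mean 0.09), with Tmem119 the 1 of 26 that fell. Fitted with the set term, 11 fell and 5 rose (lower, camera adjusted p = 2.88e-05, and adjusted p = 0.375 with an estimated correlation). C1qa, a complement C1q chain, had 0.00 and the CSF1 receptor Csf1r 0.15 (edgeR adjusted p = 1.00 for both). The transcription factor Maf had 0.93 (edgeR adjusted p = 0.126) and 0.87 with the set term (edgeR adjusted p = 0.0197), with 1.21 in the 5 other libraries and 0.15 in the lung-rich ones. Maf did not pass with the set term when WT 3 and WT 4 were summed and KO 4 was left out (0.69, edgeR adjusted p = 0.216). In KO 1, C1qa, Csf1r, H2-Ab1 and Mrc1 all lay below KO 2 to 4.

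Over all 38 lists 15 passed with the preset correlation and 0 with an estimated correlation (limma camera), 5 of the 15 passed with fry, and other splits of the libraries gave 14 to 25 lists. Of the 15, 14 passed with the set term and the preset correlation, all but complement, and 1 of them, TGF-β-induced genes, with an estimated correlation. TGF-β-induced genes had camera adjusted p = 5.85e-05 (lower) with the preset correlation, and adjusted p = 0.12 with an estimated correlation. Of 29 tested genes 0 rose, 1 fell (Pmepa1) and 28 did not pass, and 4 fell when adjusted over the list alone, with a median log2 fold change of -0.19. With the set term 10 fell and 1 rose (adjusted p = 0.0396 with an estimated correlation), and in the 5 other libraries 13 fell and 7 rose (adjusted p = 0.125 with an estimated correlation). Ldlrad4, which restrains Smad signalling, had a log2 fold change of -0.44 (edgeR adjusted p = 0.0514, and 0.00302 with the set term). It did not pass with the set term when WT 3 and WT 4 were summed and KO 4 was left out (edgeR adjusted p = 0.0595). The inhibitory Smad gene Smad7 had -0.57 (edgeR adjusted p = 0.79). It was -0.71 in the 5 other libraries and -0.02 in the lung-rich ones.

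Among TGF-β receptors and Smads, 1 of 20 tested genes fell, the ubiquitin ligase Smurf1 at 79.7 ± 1.76 against 102 ± 0.77 CPM (log2 fold change -0.35, SE 0.05, edgeR adjusted p = 0.035), 0 rose and 19 did not pass, and 2 fell when adjusted over the list alone. The camera adjusted p was 0.00124 with the preset correlation and 0.324 with an estimated correlation. Smurf1 did not pass with the set term when WT 3 and WT 4 were summed and KO 4 was left out (edgeR adjusted p = 0.0557). Tgfbr1, the partner receptor, was at 269.5 ± 50.8 CPM in Tgfbr2_KO against 559 ± 126 in WT, with no overlap (log2 fold change -1.05, SE 0.21, edgeR adjusted p = 0.122). With the set term its log2 fold change was -1.19 (edgeR adjusted p = 1.76e-04). The list of microglial genes that depend on TGF-β had 2 of 24 tested genes lower (Tmem119 and Olfml3), 0 higher and 22 not passing, and 5 higher with 7 lower when adjusted over the list alone. Its camera adjusted p was 0.0282 (lower) with the preset correlation and 0.394 with an estimated correlation. Fitted with the set term, 8 fell and 5 rose (camera adjusted p = 6.85e-05, and adjusted p = 0.112 with an estimated correlation). Without KO 1 the list did not pass (camera adjusted p = 0.470), and in the 5 other libraries 10 genes rose and 11 fell (camera adjusted p = 0.908). Gas6, a bridging ligand in the uptake of dead cells, went the other way within it (log2 fold change 1.497, edgeR adjusted p = 0.0878, and 0.00763 with the set term), with log2 fold changes of 2.10 in the 5 other libraries and 0.63 in the lung-rich ones. Gas6 did not pass with the set term when WT 3 and WT 4 were summed and KO 4 was left out (1.35, edgeR adjusted p = 0.118). For ligands and activation of TGF-β, Itgav fell, 16 of 17 genes did not pass and the list did not pass (camera adjusted p = 0.136). The integrin Itgb5 had -0.89 (edgeR adjusted p = 0.133, and 1.76e-04 with the set term) and Tgfb1 0.26 (edgeR adjusted p = 0.944).

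**Figure D4:**
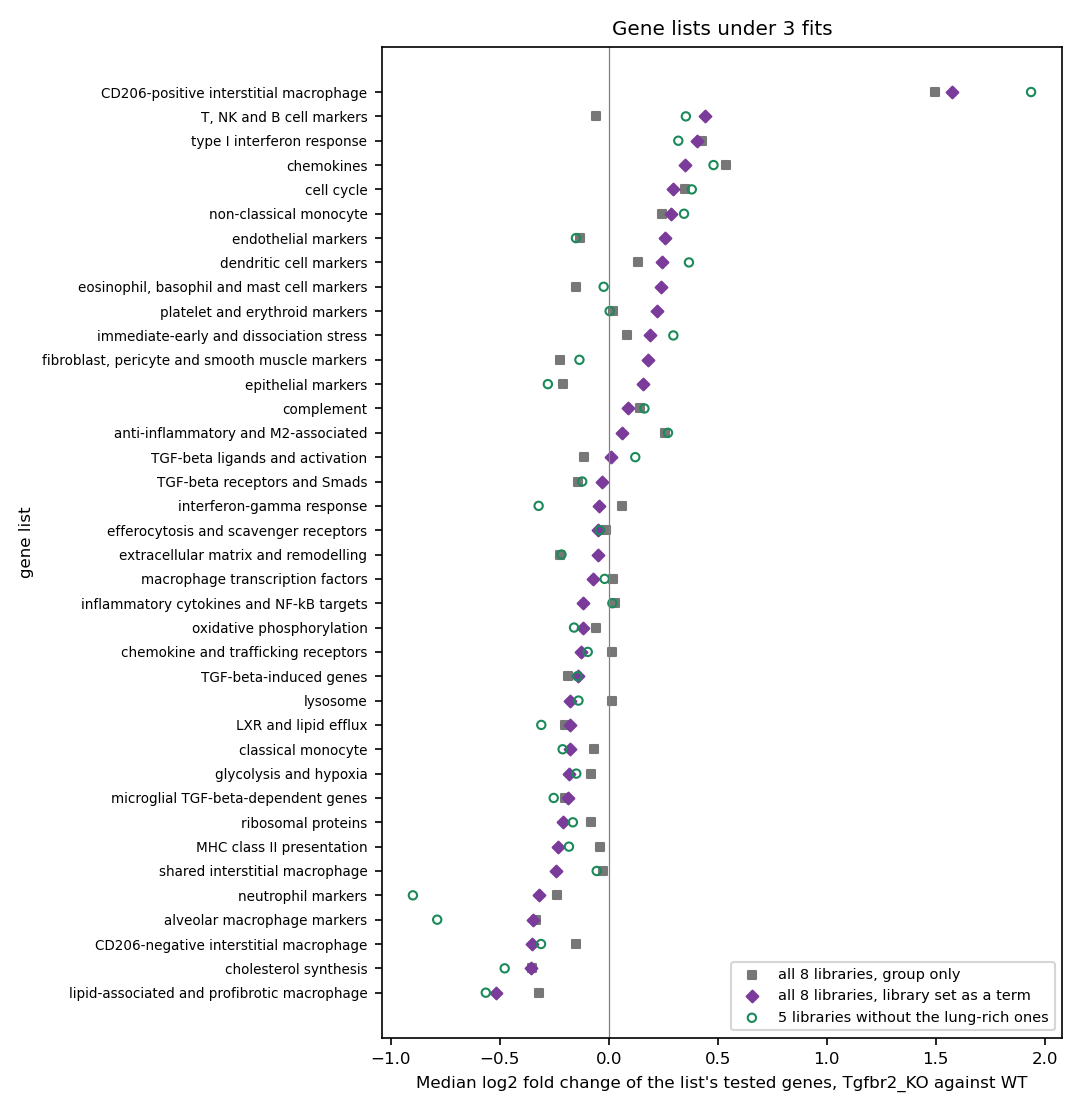
Median log2 fold change of Tgfbr2_KO against WT for each of the 38 gene lists (1 row each) under 3 fits, with grey squares for all 8 libraries with group only, purple diamonds for all 8 with the library set as a term and green circles for the 5 libraries that were not lung-rich. The CD206-positive list lies highest under each fit, with medians of 1.57 with the set term and 1.94 in the 5 libraries.

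Rtp4 of the type I interferon genes and Ccl24 of the chemokines rose in Tgfbr2_KO. In the type I interferon list 1 of 37 tested genes rose (Rtp4), 0 fell and 36 did not pass, and 8 rose when adjusted over the list alone, with a median log2 fold change of 0.43. Its camera adjusted p was 1.56e-15 (higher) with the preset correlation and 0.12 with an estimated correlation, and with the set term 20 rose and 0 fell. Rtp4, an interferon-induced chaperone, was at 31.5 ± 4.45 against 17.7 ± 0.60 CPM (log2 fold change 0.83, SE 0.10, edgeR adjusted p = 0.035), and the antiviral synthetase Oas2 had 1.29 (edgeR adjusted p = 0.0935, and 3.38e-04 with the set term). Parp14 had 0.49 (edgeR adjusted p = 0.0606). In the chemokine list 1 of 23 rose (Ccl24), 22 did not pass and 5 rose when adjusted over the list alone. Its camera adjusted p was 1.20e-04 with the preset correlation and 0.426 with an estimated correlation. The monocyte attractants Ccl2 and Ccl7 had log2 fold changes of 1.92 and 2.02 (edgeR adjusted p = 0.066 and 0.0752), with 2.30 and 2.11 in the 5 other libraries and 0.66 and 0.94 in the lung-rich ones.

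The anti-inflammatory, M2-associated list had 1 of 21 tested genes higher (Ccl24), 0 lower and 20 not passing, and 7 higher with 1 lower when adjusted over the list alone. Its camera adjusted p was 2.25e-04 with the preset correlation and 0.547 with an estimated correlation. The lectins Clec10a and Mgl2 had log2 fold changes of 2.05 and 1.49 (edgeR adjusted p = 0.066 and 0.0675, and 4.30e-04 and 0.00148 with the set term). When WT 3 and WT 4 were summed and KO 4 was left out, Clec10a passed with the set term and Mgl2 did not (edgeR adjusted p = 0.0289 and 0.0557). In the complement list 0 of 20 passed, 1 rose when adjusted over the list alone, and the camera adjusted p was 0.0482 with the preset correlation and 0.407 with an estimated correlation. Without WT 1, WT 2 or KO 3 the complement list did not pass (camera adjusted p = 0.144, 0.0578 and 0.0661), nor with the set term (0.225, with 4 genes higher and 2 lower). Properdin, encoded by Cfp, had 1.89 (edgeR adjusted p = 0.066, and 0.00162 with the set term). Cfp did not pass with the set term when WT 3 and WT 4 were summed and KO 4 was left out (edgeR adjusted p = 0.0557). Inflammatory cytokines and NF-κB targets (camera adjusted p = 0.623), the interferon-γ response (0.816, with 21 genes lower and 5 higher in the 5 other libraries) and MHC class II presentation (0.0516) did not pass. Under the fit with the set term MHC class II (6 lower, 0 higher, camera adjusted p = 4.86e-05, and adjusted p = 0.145 with an estimated correlation) and inflammatory genes (9 lower, 3 higher, 0.0402, and 0.562 with an estimated correlation) passed as lower.

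Of the cell cycle genes Kif23 rose in Tgfbr2_KO, and no cholesterol synthesis gene passed over all 8 libraries. In the cell cycle list 1 of 44 tested genes rose (Kif23), 0 fell and 43 did not pass, and 13 rose when adjusted over the list alone, with a median log2 fold change of 0.35. Its camera adjusted p was 1.64e-14 (higher) with the preset correlation and 0.255 with an estimated correlation. Kif23, a kinesin of cell division, was at 30.8 ± 2.93 against 16.2 ± 1.81 CPM (log2 fold change 0.93, SE 0.11, edgeR adjusted p = 0.0289). It did not pass with the set term when WT 3 and WT 4 were summed and KO 4 was left out (edgeR adjusted p = 0.0557). The spindle factor Tpx2 had 0.53 and cyclin A2, Ccna2, 0.43 (edgeR adjusted p = 0.0934 and 0.12). In the cholesterol list 0 of 23 tested genes passed, 5 fell when adjusted over the list alone, and the median was -0.35. Its camera adjusted p was 3.15e-09 (lower) with the preset correlation and 0.255 with an estimated correlation. Squalene epoxidase Sqle, Msmo1 and Insig1 had log2 fold changes of -0.64, -0.46 and -0.37 (edgeR adjusted p = 0.179, 0.16 and 0.185), and each passed with the set term (0.0293, 0.0203 and 0.00812). None of them passed with the set term when WT 3 and WT 4 were summed and KO 4 was left out (edgeR adjusted p = 0.178, 0.149 and 0.0815).

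Among lipid-associated and profibrotic macrophage genes Itgav fell and Mmp9 rose. Of 34 tested genes 1 fell (Itgav), 1 rose (Mmp9) and 32 did not pass, and 6 fell with 3 rising when adjusted over the list alone. The camera adjusted p was 0.0258 (lower) with the preset correlation and 0.828 with an estimated correlation, and without WT 3, WT 4 or KO 1 the list did not pass (camera adjusted p = 0.290, 0.309 and 0.842). With the set term 18 fell and 5 rose. Gpnmb of this list was at 418 and 425 CPM in WT 3 and WT 4 but at 22.8 and 62.3 CPM in WT 1 and WT 2. Within the 5 other libraries the alveolar macrophage markers were lower in Tgfbr2_KO than in WT (11 of 20 lower, 3 higher, camera adjusted p = 2.32e-16, and adjusted p = 0.133 with an estimated correlation). The tetraspanin Cd9 had a log2 fold change of -1.05 and the membrane protease Mmp14 -1.51 (edgeR adjusted p = 0.059 and 0.173, and 0.00367 and 0.00302 with the set term). Neither passed with the set term when WT 3 and WT 4 were summed and KO 4 was left out (edgeR adjusted p = 0.0598 and 0.0557). Osteopontin, Spp1, had -1.12 (edgeR adjusted p = 0.255), with -1.78 in the 5 other libraries and -0.04 in the lung-rich ones. Ribosomal protein genes had 0 of 77 tested genes past the threshold and 0 when adjusted over the list alone, with a median of -0.08. Their camera adjusted p was 0.0252 with the preset correlation and 0.986 with an estimated correlation, and without WT 3, WT 4 or KO 1 the direction reversed and the list did not pass (camera adjusted p = 0.914, 0.755 and 0.143). Of the 77 genes 51 fell and 0 rose with the set term (camera adjusted p = 6.42e-16, and adjusted p = 0.319 with an estimated correlation), and in the 5 other libraries 63 fell. The lists of oxidative phosphorylation (camera adjusted p = 0.136), glycolysis and hypoxia (0.063), lysosome (0.654), LXR and lipid efflux (0.111), efferocytosis (0.94), matrix (0.0618), trafficking receptors (0.94), macrophage transcription factors (0.673) and immediate-early genes (0.0516) did not pass. Among these, with the set term, lysosome (17 lower, 0 higher, camera adjusted p = 4.76e-08, and adjusted p = 0.319 with an estimated correlation), oxidative phosphorylation (11 lower, 1 higher, 4.86e-05, and 0.375 with an estimated correlation) and glycolysis (10 lower, 2 higher, 7.77e-04, and 0.112 with an estimated correlation) passed. So did LXR (0.00334, and 0.112 with an estimated correlation), transcription factors (0.00487 and 0.252), trafficking receptors (0.00666 and 0.121), all lower, and immediate-early genes, higher (0.0254 and 0.487). The sign of the median differed from the tested direction for transcription factors (0.02, lower), trafficking receptors (0.02, lower), lysosome (0.01, lower) and efferocytosis (-0.01, higher).

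Monocyte and other cell type markers were compared because the sorted gate could hold such cells. Non-classical monocyte genes had 0 of 24 tested genes past the threshold, 4 higher when adjusted over the list alone and a median log2 fold change of 0.25. Their camera adjusted p was 2.25e-04 (higher) with the preset correlation and 0.12 with an estimated correlation. Adgre4, an adhesion receptor of these monocytes, had 1.16 and Fabp4, a fatty acid carrier, 1.46 (edgeR adjusted p = 0.0851 and 0.0632, and 0.00119 and 0.00581 with the set term). Neither passed with the set term when WT 3 and WT 4 were summed and KO 4 was left out (edgeR adjusted p = 0.0541 and 0.0887). Classical monocyte genes did not pass as a list (camera adjusted p = 0.673, tested direction higher, median -0.07). In it Lyz1 rose, while Ly6c2 had 0.76 and Ccr2 -0.30 (edgeR adjusted p = 0.432 and 0.964). Dendritic cell markers had 0 of 25 tested genes past the threshold and 2 higher when adjusted over the list alone. Their camera adjusted p was 0.0306 with the preset correlation and 0.255 with an estimated correlation, and without WT 4 it was 0.0519. Kmo had 1.35 (edgeR adjusted p = 0.107). Alveolar macrophage markers did not pass (camera adjusted p = 0.111), and with the set term 7 fell and 2 rose (lower, camera adjusted p = 0.00354, and adjusted p = 0.375 with an estimated correlation). Chil3 and Slc7a2 of that list had -3.40 and -3.04 (edgeR adjusted p = 0.256 and 0.157), and Chil3 was at 348 and 347 CPM in WT 3 and WT 4 but at 17.5 and 30.04 CPM in WT 1 and WT 2 and 15.8 to 20.4 CPM in KO 1 to 4.

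Epithelial (camera adjusted p = 0.303), endothelial (0.264) and fibroblast, pericyte and smooth muscle markers (0.063) did not pass between the genotypes over all 8 libraries. With the set term, Sftpc, Pecam1 and the collagen gene Col1a1 had log2 fold changes of 0.08, 0.16 and 0.25 (edgeR adjusted p = 0.818, 0.62 and 0.44), and endothelial markers passed as a list (higher, camera adjusted p = 0.0243, and adjusted p = 0.628 with an estimated correlation). Neutrophil markers (camera adjusted p = 0.342), T, NK and B cell markers (0.576), eosinophil, basophil and mast cell markers (0.977, median -0.15, mean 0.61) and platelet and erythroid markers (0.977, tested direction lower, median 0.02) did not pass, although Mmp9, which is also a neutrophil gene, rose.

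The first principal component held 82.2% of the variance and separated the lung-rich libraries from the other 5, not the genotypes (exact permutation test over 70 arrangements, two-sided p = 0.8). On the second component, with 9.15% of the variance, the genotypes did not overlap (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 can give, not corrected for the choice of component). Over the 1000 most variable genes the first component gave two-sided exact permutation p = 0.743.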

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

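The tests of lung cell RNA, of donor genotype, of a mixture in KO 4, of 1 library behind WT 3 and WT 4, of Lyz2 reads counted as Lyz1, and of Lyz2 in each knockout library were chosen after the results were seen.

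KO 1 stood apart from KO 2 to 4 for 35 genes and 5 measures of the libraries. Of 166 group values tested, 44 had 1 library far from the other 3 of its group, and 40 of them were KO 1. By chance 8.3 would be, for independent values chosen without regard to the data. Many of these genes were picked by their values, Sftpc, Pecam1, Col1a1 and Ddx3y among them, so 8.3 is not a fair reference. The number in brackets is the gap to the nearest library over the range of the group (Dixon's test at the 95% level). KO 1 was lowest for Lyz2 (0.93), Cd209g (0.86), Cd209f (0.9), Mmp9 (0.97), Lyz1 (0.94), Mucl1 (0.88), Trim30c (0.87), F13a1 (0.93), Folr2 (0.97), C1qtnf1 (0.9), Itgb5 (0.84), Cd163 (0.96), Gas6 (0.88), Ccl2 (0.88), Ccl7 (0.96), Mgl2 (0.93), Mmp14 (0.9), Cfp (0.98), Kmo (0.91), Mrc1 (0.98), H2-Ab1 (0.91), Maf (0.93), C1qa (0.85), Csf1r (0.96), Tgfb1 (0.85), Itgax (0.92), Il1b (0.84), first component score (0.95). It was highest for Msmo1 (0.84), Lyve1 (0.94), Smad7 (0.91), Spp1 (0.89), Sftpc (0.99), Pecam1 (0.99), Col1a1 (0.94), genes detected (0.91), percent of counts epithelial (0.99), percent of counts endothelial (0.99), percent of counts fibroblast (0.84). Among WT, WT 1 was lowest for Lyz1 (0.92) and highest for Ccl2 (0.85) and Ddx3y (0.96), and WT 2 was lowest for Tgfbr2 (0.92). For most of these KO 1 is compared with 3 libraries of the other set, so the gaps and the library sets are 1 observation.

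The lung transcripts of WT 1, WT 2 and KO 1 covered most lung cell genes: 88.75% of the 80 epithelial, endothelial and fibroblast genes tested were higher in each of the 3 than in each other library. Sftpc reached 2815 CPM and Pecam1 726 CPM in KO 1. RNA of other lung cells, which the sort for interstitial macrophages should remove, is a candidate source. The log2 ratios of lysosome genes between WT 1 and 2 and WT 3 and 4 spread 11.4 times as widely as between WT 3 and WT 4, but these are so near counting noise that the bound set in advance was wrong, and against WT 1 and WT 2 the spread was 2.14 times (95% bootstrap interval over genes 1.79 to 2.71, a reference chosen after the result), so dilution of macrophage RNA stays open. Donor genotype is argued against by the 2 WT libraries among the 3, and a difference in sorting or preparation day stays open and untested.

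KO 2, KO 3 and KO 4, and WT 3 and WT 4, lay close together. Of the 146 genes that differed most between KO 2 and KO 3, 95.2% lay between these libraries in KO 4, against 12.3% to 24.7% in KO 1 and the WT libraries (for KO 2 and KO 3 between the other 2, on their own gene sets, 7 of 30 and 10 of 48), so shared RNA in KO 4 may be 1 source of the closeness. WT 3 and WT 4 as 1 library read 2 times is argued against by a median chi-square 1.75 times that of counting noise. No biological explanation was tested. Errors in fits of the 5 libraries and in fits with the set term, which hold the same close libraries, may be too small for this reason. With WT 3 and WT 4 summed and KO 4 left out, the set-adjusted counts fell from 1095 and 1006 to 70 and 115. In that fit 17 of the 25 and 10 of the 13 genes called over all 8 libraries still passed.

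Lyz2 was lower and Lyz1, its neighbour and paralog, higher in Tgfbr2_KO. Lyz2 reads counted as Lyz1 are argued against as the source of the whole fall of Lyz2, since the sum of both in Tgfbr2_KO was 61.3% of WT. The sum cannot tell whether part of the Lyz1 rise comes from such reads, because Lyz2 itself may be lower. Of 36 tested genes within 5 Mb of Lyz2, 13.9% passed with the set term against 16.5% elsewhere (one-sided Fisher's exact p = 0.729), too few genes to exclude an effect of flanking DNA. Lyz2 was lower in 4 of 4 knockout libraries than in every WT library. Loss of Tgfbr2 and the Cre insertion at Lyz2 cannot be told apart for this or any other gene, since every knockout donor carries both and no WT donor carries Cre.

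Other splits of the libraries were counted for the tests across genes. Of the 35 splits of 8 libraries into 4 and 4, 5 gave at least the 38 genes of the real split, the highest other 1840, so chance is not excluded for the pooled count. The 4 others put WT 1, WT 2 and KO 1 on one side, which points to the library sets as a structure of the samples. The remaining split with these libraries on one side, joined by KO 2, gave 0 genes. For gene lists 34 of 35 splits gave at least the real 15, the highest other 25, so chance is not excluded for the list count. Among the 30 splits that keep 1 knockout library among the 3 lung-rich ones, 1 (the real one) gave the real 2101 genes with the set term, the highest other 7. Of the 29 others, 27 part KO 2 to 4, which lie close together, and gave 0 genes. With 2 others that keep them whole, the splits are too few to exclude chance for that count.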

How the results depend on the processing

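The 5 libraries alone, the library set as a term, the epithelial covariate, and the fit with WT 3 and WT 4 summed and KO 4 left out were chosen after seeing the data.

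Over all 8 libraries 25 genes were higher and 13 lower. The counts were 22 and 12 with DESeq2 size factors, 22 and 13 with upper-quartile scaling, 22 and 9 without a low-count filter, 37 and 23 with a mean of at least 5 CPM, 314 and 149 with the DESeq2 Wald test, 2036 and 1767 with limma-voom and quality weights, and 17 and 3 at an absolute log2 fold change of at least 1. They were 1095 and 1006 with the set term, 2493 and 2363 in the 5 libraries, 971 and 1004 with the epithelial covariate, and 70 and 115 with WT 3 and WT 4 summed and KO 4 left out. Leaving out 1 library gave 0 to 619 higher and 0 to 241 lower genes by edgeR (807 to 3476 at an unadjusted p under 0.05), with the calls all from the fit without KO 1. Of 27 named genes past the threshold, 27 passed with DESeq2, voom, the 5 CPM filter, the set term, the epithelial covariate, the 5 libraries and without KO 1. Of them 24 passed with DESeq2 size factors, 24 with upper-quartile scaling, 22 without a low-count filter, 20 with WT 3 and WT 4 summed, 15 at an absolute log2 fold change of at least 1, and 0 (edgeR) without any 1 of the other 7 libraries. Their direction reversed under none of these. The cause of the spread between tools was not tested.

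Replicate numbers as a block gave 0 higher and 0 lower genes by edgeR, with 1479 at an unadjusted p under 0.05 and 22 lists, and 0 of the 27 named genes passed, with 0 reversed. Pairing was checked: correlations of same-numbered libraries were 0.87, -0.79, 0.69 and 0.75. Libraries of the same set with different numbers gave similar values, such as 0.88 for WT 2 and KO 1. The signs follow the library sets, so the check cannot tell whether the numbers pair the libraries.

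Lyz2 passed, in the same direction, with DESeq2 (-1.06, adjusted p = 0.00664), voom (-1.19, adjusted p = 6.53e-05), the 5 libraries (-1.24, adjusted p = 2.39e-18), the set term (-1.22, adjusted p = 0.000147), the epithelial covariate (-1.19, adjusted p = 2.28e-05) and WT 3 and 4 summed (-1.24, adjusted p = 0.0247). Without 1 library its log2 fold change ranged from -1.19 to -0.91, and it passed in 0 of these fits. Log2 fold changes of these genes changed sign, none past the threshold under an alternative that reversed it. Tgfbr2 was 0.0056 with voom, 0.013 with the 5 libraries, and -0.093 to 0.054 without 1 library. H2-Ab1 was -0.19 to 0.16 without 1 library. C1qa was -0.0042 with DESeq2 size factors, -0.0039 with the 5 CPM filter, -0.0019 with DESeq2, -0.0068 with voom, -0.047 with the replicate block, -0.030 with the 5 libraries, -0.24 with the set term, -0.23 with the epithelial covariate, -0.36 with WT 3 and 4 summed, and -0.11 to 0.21 without 1 library. Csf1r was -0.047 with the set term, -0.039 with the epithelial covariate, -0.18 with WT 3 and 4 summed, and 0.066 to 0.34 without 1 library. Tgfb1 was -0.027 with WT 3 and 4 summed, and 0.14 to 0.43 without 1 library. Sftpc was 0.085 with the set term, 0.19 with WT 3 and 4 summed, and -3.44 to 0.35 without 1 library. Pecam1 was 0.16 with the set term, 0.25 with WT 3 and 4 summed, and -2.99 to 0.40 without 1 library. Col1a1 was 0.25 with the set term, 0.098 with the epithelial covariate, 0.29 with WT 3 and 4 summed, and -1.86 to 0.24 without 1 library. Ddx3y was 0.51 with the 5 libraries, and -4.13 to 0.62 without 1 library. The cause was not tested.

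Of 38 gene lists 15 passed, and 14 to 23 without 1 library, 26 with the set term, 26 with the epithelial covariate, 26 in the 5 libraries, 27 with WT 3 and WT 4 summed and 5 with fry. Of the 15, 13 still passed in the same direction with the 5 CPM filter and 13 with WT 3 and WT 4 summed. The set term, the epithelial covariate and the 5 libraries each kept 14. With an estimated correlation 0 passed over all 8 libraries, 1 with the set term (TGF-β-induced) and 2 in the 5 libraries (CD206-positive and chemokines); it was not run in the other fits. Of the 15, 5 lists kept their direction but were lost without 1 library: microglial (0.470 without KO 1), CD206-negative (0.641 without KO 1), lipid-associated (0.290, 0.309 and 0.842 without WT 3, WT 4 and KO 1), complement (0.144, 0.0578 and 0.0661 without WT 1, WT 2 and KO 3) and dendritic cell (0.0519 without WT 4). Lists whose direction reversed follow, with the camera adjusted p at the preset correlation. Ranges without 1 library cover all 8 such fits, reversed or not. Among those fits the only reversal past the threshold was lysosome without KO 1 (higher, camera adjusted p = 0.0363). The fibroblast list and the T, NK and B cell list reversed in none of them. Shared interstitial macrophage: 0.793 with the replicate block, 2.88e-05 with the set term (adjusted p = 0.375 with an estimated correlation), 8.35e-06 with the epithelial covariate, 1.21e-06 with WT 3 and 4 summed, and 0.00232 to 0.900 without 1 library. Classical monocyte: 0.00433 with the 5 libraries (adjusted p = 0.417 with an estimated correlation), 0.221 with the set term, 0.551 with the epithelial covariate, 0.270 with WT 3 and 4 summed, and 0.0519 to 0.954 without 1 library. MHC class II presentation: 0.00575 to 0.994 without 1 library, reversed only without KO 1 (0.994). Macrophage transcription factors: 0.138 to 0.755 without 1 library. Inflammatory cytokines and NF-κB targets: 0.0402 with the set term (adjusted p = 0.562 with an estimated correlation), 0.0406 with the epithelial covariate, 0.00324 with WT 3 and 4 summed, and 0.000548 to 0.989 without 1 library. Interferon-gamma response: 1.75e-06 with the 5 libraries (adjusted p = 0.158 with an estimated correlation), 0.789 with the set term, and 0.111 to 0.505 without 1 library. Chemokine and trafficking receptors: 0.233 to 0.813 without 1 library. Efferocytosis and scavenger receptors: 0.557 with the 5 CPM filter, 0.750 with the replicate block, 0.0505 with the set term, 0.0396 with the epithelial covariate, 0.0612 with WT 3 and 4 summed, and 0.335 to 0.993 without 1 library. Oxidative phosphorylation: 0.000553 to 0.774 without 1 library, reversed only without WT 3, WT 4 and KO 1 (0.629, 0.434 and 0.774). Lysosome: 0.00963 to 0.260 without 1 library, reversed only without WT 3, WT 4 and KO 1 (0.260, 0.232 and 0.0363). Ribosomal proteins: 9.23e-06 to 0.914 without 1 library, reversed only without WT 3, WT 4 and KO 1 (0.914, 0.755 and 0.143). Neutrophil markers: 0.914 with fry, and 0.000281 to 0.941 without 1 library, where only the fit without WT 3 reversed (0.941). T, NK and B cell markers: 0.143 with the set term, 0.288 with the epithelial covariate, 0.0477 with WT 3 and 4 summed, and 0.0452 to 0.994 without 1 library. Eosinophil, basophil and mast cell markers: 0.818 with the replicate block, 0.470 with the 5 libraries, 0.986 with the set term, 0.740 with the epithelial covariate, and 0.704 to 0.981 without 1 library. Endothelial markers: 0.0243 with the set term (adjusted p = 0.628 with an estimated correlation), 0.432 with the epithelial covariate, 0.000215 with WT 3 and 4 summed, and 0.000185 to 0.996 without 1 library. Epithelial markers: 0.415 with the set term, 0.0367 with WT 3 and 4 summed, and 0.000219 to 0.954 without 1 library. Fibroblast, pericyte and smooth muscle markers: 0.490 with the set term, 0.146 with WT 3 and 4 summed, and 0.000105 to 0.739 without 1 library. Platelet and erythroid markers: 0.975 with DESeq2 size factors, 0.460 with the 5 CPM filter, 0.0505 with the 5 libraries, 0.172 with the set term, 0.162 with the epithelial covariate, 0.0480 with WT 3 and 4 summed, 0.914 with fry, and 0.214 to 0.786 without 1 library. The cause was not tested.

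Changes of 1.5, 2 and 4 times were simulated to see what spread and depth limit. The simulated libraries were independent and had the dispersions of the fit with the set term. They held no close libraries, so the rates for the set term and the 5 libraries may not hold for the real data. With group only, 26.9%, 43.3% and 75.8% of genes changed by the 3 simulated folds, smallest first, were recovered with 0 false calls. With the set term 68.7%, 83.6% and 92.4% were recovered with 10 false calls, and in the 5 libraries 53.7%, 68.7% and 89.4% with 17.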

Other observations

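The counts of list means by permutation were chosen after the results were seen.

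Gpnmb and Chil3 were high in WT 3 and WT 4 and not in WT 1 and WT 2, which was seen in the values and not tested. Gpnmb, a glycoprotein of lipid-laden macrophages, was at 22.8 and 62.3 CPM in WT 1 and WT 2 and at 418 and 425 CPM in WT 3 and WT 4. Its log2 fold change in Tgfbr2_KO was -2.37 in the 5 libraries and -0.20 in the lung-rich ones. Chil3, a chitinase-like protein of alveolar macrophages, had -4.38 and -0.30. In the 5 libraries 11 of 20 alveolar macrophage markers were lower and 3 higher in Tgfbr2_KO than in WT (edgeR), with a median log2 fold change of -0.79.

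Y-linked genes (Ddx3y and 3 others) summed to 967 counts, 62.0 CPM, in WT 1 and to 0 to 6.54 CPM in the other libraries, although the labels give female mice for all.

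Mmp9 (chromosome 2, 164940780 to 164955850) and Slc12a5 (chromosome 2, 164960802 to 164999731) are neighbours on the plus strand, and both rose (log2 fold changes 3.53 and 2.81).

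Of the 12750 tested genes 880 (6.90%) did not overlap between the genotypes, where chance would give 2.86% if all 8 libraries were exchangeable, which the library sets and the close libraries argue against. Permuting genotype within the library sets, the mean log2 fold change of 19 of the 38 lists had an exact permutation p = 0.0333, the smallest that 30 arrangements can give, with adjusted p = 0.0667 for these. Only 2 of the other arrangements keep KO 2 to 4 together. The 19 lists included TGF-β-induced, CD206-positive, CD206-negative, type I interferon, chemokine and cell cycle genes, and did not include TGF-β receptors, microglial, complement or cholesterol genes.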
